A study of Mus musculus with 48 samples.

How the data were processed

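Methylated DNA was captured with a methyl-CpG-binding domain (MethylMiner) from the duodenum, jejunum, ileum and colon of 12 mice, 7 labelled GermFree and 5 labelled ConvR (conventionalised), and sequenced as 48 libraries, 1 per mouse and section. Groups, sections and mouse numbers were taken from the sample characteristics, and a code from the sample titles. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.3.7 and cutadapt 1.4.2, and MACS2 and featureCounts were used with the mouse build mm10. The aligner, the handling of duplicates and of reads that match several places, and how libraries were pooled for peak calling are not given in the sources used here. All region names carry the GermFree label, so regions with more captured DNA in ConvR mice are under-represented if the peaks were called on GermFree libraries.

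The deposited table of counts holds the whole-number reads per region for 95882 regions in the 48 libraries, with no normalisation. The deposited peak list gives the position of each region and 1 score per region, which is the authors' own value and was used only to filter regions in an alternative. Library totals had a median of 2122529 counts and the median region held between 7 and 23 counts, so single regions were measured with limited precision and much of the work rests on groups of regions.

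Regions were matched to genes with a RefSeq gene table of the assembly GRCm38.p6, which has the coordinates of mm10. A region was assigned to a gene when it overlapped the gene or lay within 5 kb of it, and otherwise to the nearest gene within 50 kb for naming only. The plan was to use 5 kb upstream of gene starts and classes of promoter, exon and intron. The gene table used here has neither strand nor exons, so both sides of a gene were used, and the classes were within 1 kb of a gene end, gene body away from its ends, and outside genes, together with the class of chromosome. Of 593 genes in 23 gene lists, 591 matched by symbol.

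Counts were analysed with edgeR 4.0.16 in R 4.3.3 (TMM factors, the default count filter, trended dispersion, quasi-likelihood F-tests, Benjamini-Hochberg adjustment over tested regions, threshold 0.05), with data.table, version 1.17.8, for tables. GermFree and ConvR mice were compared in each section on its 12 libraries, and on counts summed over the 4 sections of a mouse, so that the mouse was the replicate. Sections were compared over all 48 libraries with 8 groups of model and section, and a joint test of 3 contrasts asked whether the difference between models varied by section. These designs, the lists, the alternatives and the rule for named genes were written before the data were examined. Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between regions, and again with an estimated correlation and with fry. The share of counts in each class was compared by an exact permutation test over all 792 relabellings of 7 and 5 mice, whose smallest two-sided p is 0.00126. DESeq2 1.42.0 was run as a second tool. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used for annotation, shares and figures. Values in the text are TMM-normalised CPM, the count of a region scaled to the size of its library, as mean and SD over mice.

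The rule for named genes took, among regions past the threshold with a mean of at least 1 CPM, up to 10 with the largest log2 difference in each direction, 1 per gene or per 100 kb without a gene. Where fewer than 5 regions passed, the 5 with the smallest p were named. For a list that passed, up to 4 members were added, and for the list of natural killer receptors and activation genes up to 6 members in every section. From these the text names a part. Members of other lists that passed, and the clusters of regions, were chosen after their values were seen.

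Each mouse gave all 4 sections, so libraries with the same mouse number and model pair the section comparisons, and a fit with the mouse as a block was run beside them. The deviations of such libraries from their group means had a median correlation of 0.0201 over 72 pairs. Other alternatives were other scalings (DESeq2 size factors, library totals, offsets fitted to abundance), no count filter, stricter score filters, autosomes only, blocks by mouse number and by the code in the titles, 1 model alone, and leaving out each mouse in turn. Alternatives without the regions of the clusters, with scores at or above the median, without ConvR mice 1 and 3 (with and without the mouse as a block), and with the Y chromosome share as a covariate were added after the data were seen. The edgeR and list steps were tested on simulated data with the means and library sizes of the real regions and 200 changed regions before they were run on the counts. Regions in the deposited table were used in full, and no library was left out of the comparisons.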

Results

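DNA methylation along the mouse intestine was profiled by capturing methylated fragments with a methyl-CpG-binding domain and sequencing the captured DNA (MBD-seq). A higher normalised count at a region means more captured DNA there, which depends on how methylated the region is and on how many copies of it the genome holds. The 48 libraries came from 12 mice, 7 germ-free (GermFree) and 5 conventionalised (ConvR), and each mouse gave 1 library from the duodenum, jejunum, ileum and colon. The replicates were therefore separate mice, and in the main comparisons of GermFree with ConvR mice the 4 libraries of a mouse were not counted as independent. The main fits between sections and of the variation by section had no term for the mouse. Fits with the mouse as a block are given beside them. Counts covered 95882 regions with a median width of 1208 bp, of which 66670 (69.5%) overlapped an annotated gene. Library totals ran from 1007560 (ConvR ileum, mouse 1) to 3033782 (ConvR duodenum, mouse 5) with a median of 2122529. Mean totals were 2.12 M ± 0.297 (SD, n = 7) in GermFree and 2.13 M ± 0.802 (SD, n = 5) in ConvR duodenum, and 2.16 ± 0.564 and 2.04 ± 0.758 in the ileum. The median correlation of a library with the others of its group lay between 0.783 and 0.871. The median region held 7 counts in the shallowest and 23 in the deepest library.

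The first comparison asked where captured DNA differed between GermFree and ConvR mice, with attention to genes that control natural killer lymphocytes, the subject of the series title. Over the 4 sections of each mouse summed, GermFree mice had higher normalised counts across several gene families. These were the Klra genes, which encode the Ly49 receptors of natural killer cells, the genes H60b, Raet1d and Raet1e, which encode ligands of the activating natural killer receptor NKG2D, and the Btbd35f and Spin2 families of the X chromosome. The region over H60b (mm10 chromosome 10, 22278837 to 22288912) gave 144 ± 39.9 CPM in GermFree mice (SD, n = 7) and 37.1 ± 7.13 in ConvR mice (SD, n = 5), a log2 difference of 1.95 (SE 0.13; edgeR adjusted p = 1.16e-13), with 7 of 7 GermFree mice above all ConvR mice. A region inside Cr2, which encodes a complement receptor of B cells (chromosome 1, 195149833 to 195155000), gave 32.0 ± 6.27 against 18.7 ± 2.82 (log2 0.76, SE 0.10; edgeR adjusted p = 2.78e-07), and 5 of the 5 Cr2 regions that passed were higher. The largest difference upward was at the predicted gene Gm14356 (chromosome X, 4193443 to 4194645), with 13.1 ± 6.59 against 2.13 ± 0.825 and a log2 difference of 2.61 (SE 0.29). Of 95882 regions tested with edgeR, 455 passed, 413 of them higher and 42 lower in GermFree mice, and 6358 had an unadjusted p under 0.05. All region names carry the GermFree label, and if the regions were called on GermFree libraries, those with more captured DNA in ConvR mice are under-represented. DESeq2 called 364. On simulated data with the same means and depths, edgeR recovered 100% of regions changed by a log2 of 1 and 44.8% of those changed by 0.5 in this comparison. The simulation set the coefficient of variation between mice to 0.1, against 0.0593 estimated for the sums, and let regions vary independently. These rates are therefore approximate. Klra, Raet1, Btbd35f, Spin2 and Mup are families of similar gene copies, and the way reads were placed among such copies is not given in the sources used here, so the values of single members are uncertain.

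The passing regions lay close together. Grouping passing regions with gaps of at most 500 kb into clusters of 5 or more, a step taken after the calls were seen, gave 12 clusters that held 352 of the 455 calls but 423 (0.441%) of the regions. All 352 were higher in GermFree mice. The X chromosome stretch from 31130368 to 34560986, with genes such as Btbd35f26 and Spin2f, held 108 passing regions of 113, and its summed count, averaged over the 4 sections, was 3629 ± 1408 CPM in GermFree mice (SD, n = 7) against 1226 ± 239 in ConvR mice (SD, n = 5). The second X chromosome stretch, from 3051711 to 5392838, held 69 passing regions of 74. The Klra stretch on chromosome 6 from 129848474 to 131021287 held 71 of 83, with 4682 ± 498 against 2815 ± 447. Its last Klra gene, Klra1, ends at 130386874, and many passing regions lay beyond it. The protein-coding genes there were Gm6590, Gm38706, Gm6600 and LOC115490339, so the sum is not a level of the Klra genes alone. The stretch with Raet1e, H60b and Raet1d on chromosome 10, from 22149251 to 22594287, held 27 of 35, with 1156 ± 239 against 489 ± 71.1. The stretch at Cr2 on chromosome 1, from 195139473 to 195335828, held 17 of 19, and all 12 regions passed in the stretch on chromosome 2, from 24661151 to 24802813, at Cacna1b, a neuronal calcium channel gene, and Ehmt1, a histone methyltransferase gene. The others were at Rasgrp3 and Fam98a, at the major urinary protein genes (Mup), at Mndal and other interferon-inducible genes, at the complement protease genes C1ra and C1s1, at Mid1 near the end of the X chromosome, and near the end of the Y chromosome. In the means over the 4 sections, 7 of 7 GermFree mice lay above all ConvR mice at the Klra, Raet1 and Ehmt1 stretches and 6 of 7 did at the large X chromosome stretch, all of them chosen for this difference. GermFree mouse 3 lay inside the ConvR range at both large X chromosome stretches in 4 of 4 sections. Fitted without the regions of these clusters, edgeR called 67 regions.

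**Figure D1:**
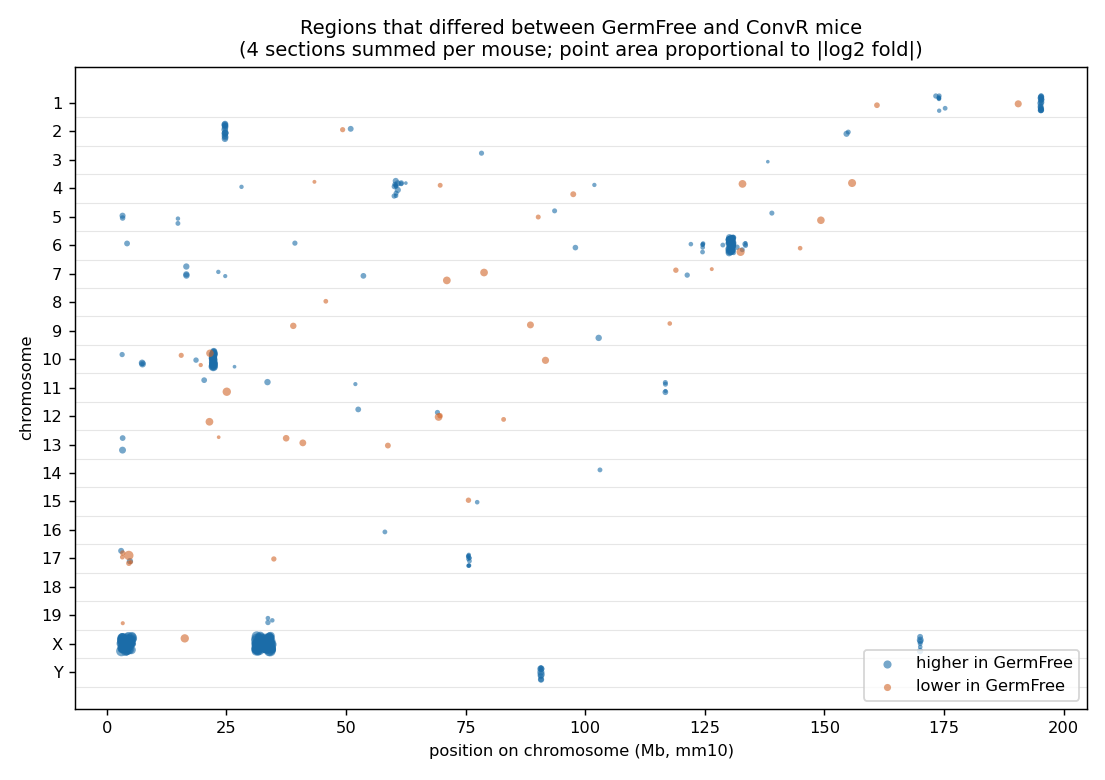
Position in mm10 (Mb, horizontal) and chromosome (vertical) of the regions that passed the edgeR test between GermFree (n = 7) and ConvR (n = 5) mice with the 4 sections of each mouse summed; each point is a region, its area is proportional to the size of the log2 difference and its colour gives the direction. Of the 413 regions higher in GermFree mice, 352 sat in 12 clusters, and the 42 lower regions were scattered.

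Of the 65 genes in the list of natural killer receptors and activation genes, 43 had a tested region in the sums, and 12 of these had a region that rose in GermFree mice: H60b, Klra1, Klra3, Klra4, Klra7, Klra8, Klra9, Klra10, Klra17, Raet1d, Raet1e and Ulbp1. The region over Klra7 (chromosome 6, 130214425 to 130219298) gave 54.6 ± 6.85 CPM in GermFree mice (SD, n = 7) and 24.2 ± 5.36 in ConvR mice (SD, n = 5; log2 1.17, SE 0.09; edgeR adjusted p = 4.84e-12). Klra4 (chromosome 6, 130042204 to 130053893) gave 99.0 ± 11.9 against 45.8 ± 8.39, and the region within 5 kb of Raet1d (chromosome 10, 22355369 to 22361158) 50.1 ± 10.5 against 19.4 ± 2.53. None of the members outside these families passed, among them the interferon gamma gene Ifng, the granzyme gene Gzma, the adaptor genes Hcst and Tyrobp and the receptor genes Klrb1c and Klrg1. Within the families Klra5, inside the Klra stretch, and H60c, outside the stretch with H60b, were tested and did not pass. Of the 133 regions of the list 33 passed, all higher, and 42 passed when adjusted over the list alone. The list passed its set test (adjusted p = 1.63e-36 with the preset correlation, 0.00567 with an estimated correlation), and without the regions of the 12 clusters it did not (adjusted p = 0.681). The clusters were chosen for a difference in these same libraries and held 32 of the 33 passing regions, so this loss was close to fixed in advance. The list was drawn up because the series title names these cells, so it is not independent evidence of their direction. Of the other 22 lists none passed, with B cells and plasma cells nearest (adjusted p = 0.0685, 0.0401 with an estimated correlation), where the 5 passing regions were those at Cr2. Outside it, Cpt1a, the gene of the enzyme that admits fatty acids to mitochondria, was the one further list member to pass, and its region (chromosome 19, 3364273 to 3366708) fell by 0.37 on the log2 scale, from 14.7 ± 1.001 in ConvR to 11.4 ± 1.08 in GermFree mice (edgeR adjusted p = 0.0164). Cpt1a was chosen after its values were seen, and it did not pass without ConvR mouse 2 (log2 -0.32) or 4 (-0.35) or GermFree mouse 6 (-0.33) or 7 (-0.35).

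**Figure D2:**
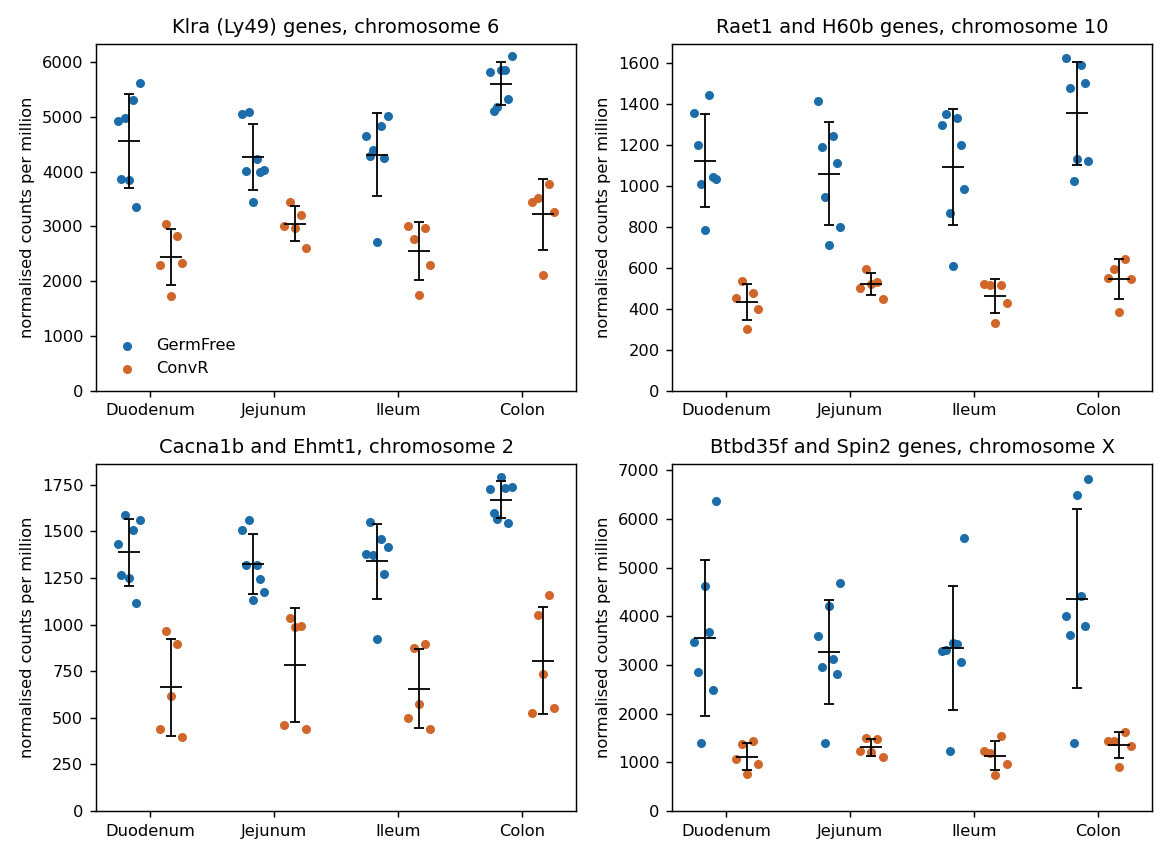
Normalised CPM summed over the regions of 4 of the clusters (vertical axes, starting at 0) in each section, with 1 point per mouse for 7 GermFree and 5 ConvR mice and bars giving the mean and SD. In the colon the Klra cluster averaged 5605 ± 394 in GermFree and 3218 ± 648 in ConvR mice. At the X chromosome cluster 1 GermFree mouse lay among the ConvR mice in each section. GermFree mouse 4 did so at the Klra cluster in the jejunum (3435) and ileum (2712). The Klra cluster also holds regions beyond the last Klra gene.

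**Figure D3:**
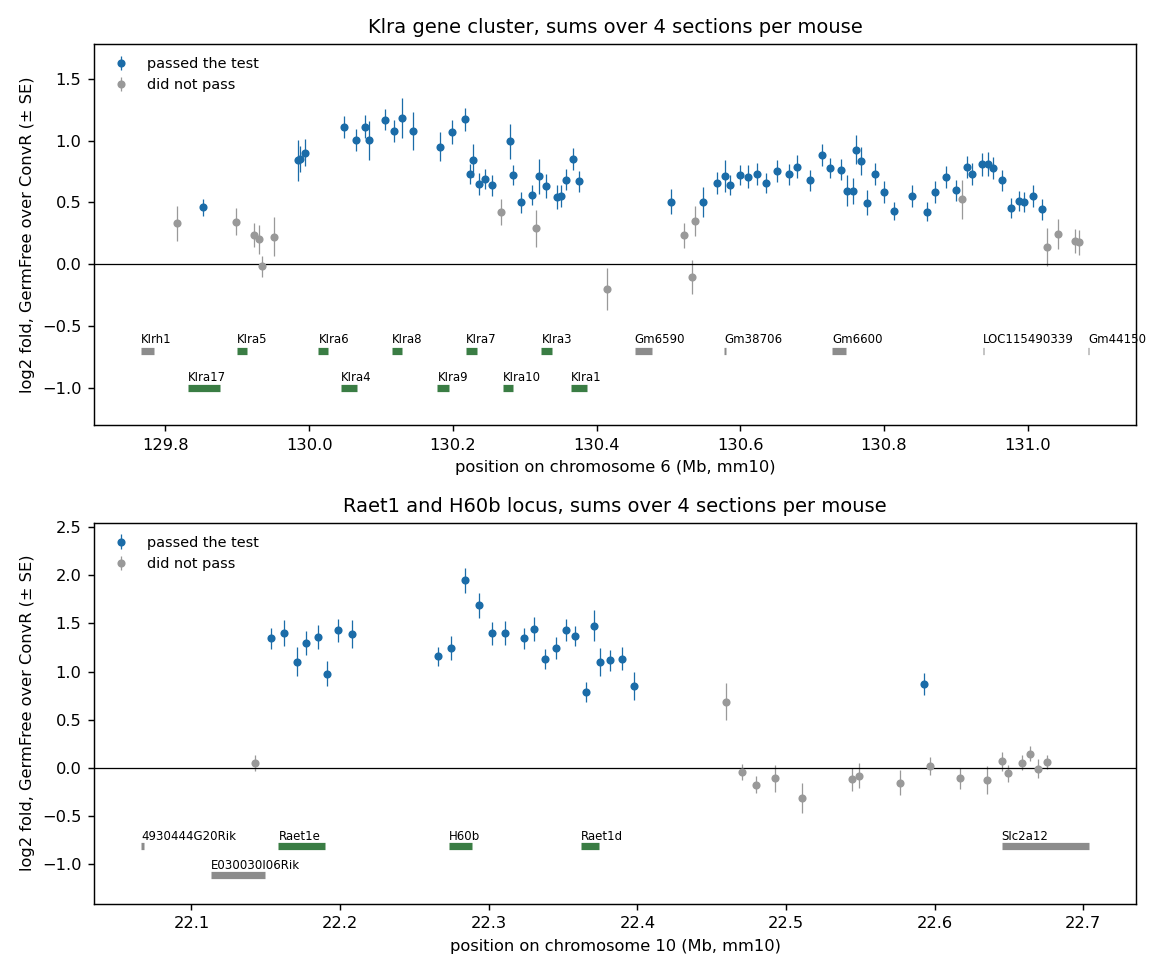
Log2 difference between GermFree and ConvR mice (vertical, with SE) of each region against its mm10 position (Mb, horizontal) at the Klra cluster and at the Raet1 and H60b locus, from counts summed over 4 sections; blue points passed the edgeR test, bars under the points are genes. At the Klra locus 71 of the 88 regions drawn passed and at the Raet1 and H60b locus 27 of 45, all higher in GermFree mice. Many of those at the Klra locus lay beyond Klra1, the last Klra gene.

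In the duodenum the same natural killer gene families stood out. H60b gave 160 ± 43.1 CPM in GermFree (SD, n = 7) and 36.4 ± 7.81 in ConvR mice (SD, n = 5; log2 2.13, SE 0.15; edgeR adjusted p = 7.52e-17). Raet1e gave 87.9 ± 17.8 against 30.3 ± 9.95 and Klra9 (chromosome 6, 130187367 to 130211212) 396 ± 80.6 against 166 ± 35.1. Btbd35f23 on the X chromosome (3082614 to 3086643) gave 33.8 ± 21.5 against 6.09 ± 1.75 (log2 2.38, SE 0.28). The largest fall was at Gm34259 (chromosome 17, 4625871 to 4626954), from 57.4 ± 66.0 in ConvR to 10.4 ± 8.66 in GermFree mice, log2 -2.13 (SE 0.40; edgeR adjusted p = 0.000564), and Kmt2c, a histone methyltransferase gene (chromosome 5, 25383381 to 25383969), went from 8.18 ± 4.21 to 3.20 ± 1.34 (log2 -1.25, SE 0.30). Of 75328 regions tested with edgeR 349 passed, 319 higher and 30 lower, and DESeq2 called 221. In the natural killer list 28 of 112 regions at 10 genes passed, all higher, and 36 passed when adjusted over the list alone (set test adjusted p = 4.18e-35, 0.00558 with an estimated correlation). The smallest adjusted p of the other 21 lists was 0.150. Without ConvR mouse 1 neither Gm34259 (log2 -1.46) nor Kmt2c (-1.04) passed, and without GermFree mouse 2 Kmt2c did not (-1.15). Without ConvR mice 1 and 3, a choice made after the levels were seen that leaves 3 ConvR mice, edgeR called 7 lower regions, and the log2 difference at Gm34259 was -0.06.

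In the jejunum H60b gave 144 ± 42.5 CPM in GermFree (SD, n = 7) and 41.5 ± 6.88 in ConvR mice (SD, n = 5; log2 1.77, SE 0.12; edgeR adjusted p = 7.46e-29). Raet1e gave 82.0 ± 19.99 against 37.9 ± 5.87, Klra8 (chromosome 6, 130109734 to 130126450) 140 ± 20.96 against 77.7 ± 11.4 and Klra9 349 ± 45.9 against 198 ± 26.3 (log2 0.82, SE 0.10). The predicted gene Gm46188 (chromosome 10, 15579884 to 15582781) fell by 1.10 on the log2 scale, from 30.9 ± 7.19 in ConvR to 14.5 ± 5.05 in GermFree mice (edgeR adjusted p = 6.22e-10), with 6 of 7 GermFree mice below all ConvR mice. Of 81883 regions tested with edgeR 281 passed, 249 higher and 32 lower, and DESeq2 called 143. In the natural killer list 23 of 120 regions at 9 genes passed, all higher, and 30 when adjusted over the list alone (set test adjusted p = 2.74e-20, 0.00778 with an estimated correlation). The smallest adjusted p of the other 21 lists was 0.249. Fitted together with the libraries of the other sections, 179 regions passed, and without ConvR mice 1 and 3 the lower regions numbered 16.

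In the ileum H60b gave 139 ± 49.4 CPM in GermFree (SD, n = 7) and 37.7 ± 8.11 in ConvR mice (SD, n = 5; log2 1.86, SE 0.17; edgeR adjusted p = 1.14e-11). Raet1d gave 51.9 ± 12.8 against 18.5 ± 4.72, Klra8 141 ± 27.3 against 59.3 ± 17.0 and Klra7 54.3 ± 12.9 against 22.7 ± 6.07. Cr2 had 4 passing regions, all higher, of which that from 195180491 did not pass without ConvR mouse 3 (log2 0.56) or 5 (0.60) or GermFree mouse 5 (0.60) or 7 (0.54), and that from 195163667 without ConvR mouse 5 (0.62). Captured DNA fell at Gm34259, from 43.99 ± 52.9 in ConvR to 5.45 ± 4.50 in GermFree mice (log2 -2.73, SE 0.41; edgeR adjusted p = 4.59e-06), and at Rn7s2, a gene of the signal recognition particle RNA (chromosome 12, 69360834 to 69363164), from 50.4 ± 56.8 to 11.8 ± 6.74 (log2 -1.81, SE 0.33). Of 85464 regions tested with edgeR 312 passed, 270 higher and 42 lower, and DESeq2 called 163, none of them lower. In the natural killer list 27 of 122 regions at 11 genes passed, all higher, and 39 when adjusted over the list alone (set test adjusted p = 2.62e-28, 0.0109 with an estimated correlation). The smallest adjusted p of the other 22 lists was 0.303. The 42 lower regions were high mainly in ConvR mice 1 and 3, where 41 and 40 of them lay above the GermFree mean by more than 2 SD, against 4 in ConvR mice 2 and 4 and 28 in mouse 5. Without ConvR mice 1 and 3, 3 of the 42 passed.

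In the colon H60b gave 176 ± 38.7 CPM in GermFree (SD, n = 7) and 44.6 ± 11.8 in ConvR mice (SD, n = 5; log2 2.0, SE 0.13; edgeR adjusted p = 4.72e-25). Raet1e (chromosome 10, 22160236 to 22164160) gave 52.7 ± 11.6 against 16.6 ± 3.52, Klra7 71.6 ± 3.53 against 30.2 ± 6.51 and Klra4 130 ± 14.4 against 56.3 ± 15.8. The region in Myh2, a skeletal muscle myosin gene (chromosome 11, 67192712 to 67194956), fell from 15.9 ± 1.98 in ConvR to 8.42 ± 1.21 in GermFree mice (log2 -0.91, SE 0.18; edgeR adjusted p = 0.000506), with 7 of 7 GermFree mice below all ConvR mice. Among members of the other lists, named here because they passed, Pou2f3, the tuft cell transcription factor gene (chromosome 9, 43153453 to 43158359), rose from 19.4 ± 2.75 to 28.9 ± 3.51 (log2 0.57, SE 0.14; edgeR adjusted p = 0.0120), and Ifnar1, a type I interferon receptor gene (chromosome 16, 91504803 to 91507033), fell from 15.96 ± 4.68 to 10.04 ± 2.34 (log2 -0.71, SE 0.18; edgeR adjusted p = 0.0296). Pou2f3 did not pass without ConvR mouse 1 (log2 0.53) or 3 (0.50) or GermFree mouse 4 (0.53), and Ifnar1 did not without ConvR mouse 3 (-0.48) or GermFree mouse 1 (-0.69), 2 (-0.65), 5 (-0.65) or 6 (-0.68). Of 74230 regions tested with edgeR 402 passed, 381 higher and 21 lower, and DESeq2 called 246. In the natural killer list 31 of 115 regions at 11 genes passed, all higher, and 37 when adjusted over the list alone (set test adjusted p = 1.89e-39, 0.000314 with an estimated correlation). The smallest adjusted p of the other 21 lists was 0.478. Without ConvR mice 1 and 3 edgeR called 12 lower regions.

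Of the regions called in any section, 528 in all, 199 passed in all 4 sections and 198 of these were higher in GermFree mice, while 184 passed in 1 section. The duodenum and colon shared 287 calls, all in the same direction, where independent lists would share 1.91. The libraries of the 4 sections came from the same mice. Whether the difference between GermFree and ConvR mice varied with the section was tested directly. The smallest p-values belonged to Wdfy3, an autophagy scaffold gene, Tiam1, a Rac activator gene, and Satb1, a chromatin organiser gene of T cells, and none passed (edgeR adjusted p = 0.986 for each). With edgeR 0 regions passed and 4746 had an unadjusted p under 0.05, and DESeq2 called 0. With the mouse as a block 13 passed, among them Gm34259, Gm24105 and Il5, the interleukin gene of eosinophil growth, named here because they passed. The Il5 region (chromosome 11, 53721594 to 53722378) gave 18.6 ± 19.9 CPM in ConvR duodenum (SD, n = 5) and 5.31 ± 4.70 in GermFree duodenum (SD, n = 7), and 5.93 ± 2.20 against 5.26 ± 2.42 in the colon. At all 13 regions ConvR mice 1 and 3 had the 2 highest levels of the 12 mice in the duodenum and ileum, and without them none of the 13 passed with the mouse as a block.

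The share of a library's counts on the X chromosome was higher in GermFree mice in the means of all 4 sections, although 0 of 28 tests of shares passed the correction. In the duodenum the X share was 0.834% ± 0.232 (SD, n = 7) in GermFree and 0.462% ± 0.0672 (SD, n = 5) in ConvR mice, higher in 7 of 7 (exact permutation p = 0.00379, adjusted p = 0.0619). In the colon it was 0.966% ± 0.253 against 0.537% ± 0.0757, with 6 of 7 GermFree mice above all ConvR mice (exact permutation p = 0.00884, adjusted p = 0.0619). Most of this difference lay in the clusters described above. They were chosen for a difference between the models in these same libraries, so leaving them out was bound to shrink the difference in share. Without the X chromosome regions inside them, a check added after the data were seen, the share was 0.318% ± 0.0389 against 0.282% ± 0.0309 in the duodenum (exact permutation p = 0.120) and 0.361% ± 0.0138 against 0.332% ± 0.0444 in the colon (exact permutation p = 0.0758). The share in gene bodies away from their ends was 50.8% ± 0.330 against 51.7% ± 0.726 in the colon (exact permutation p = 0.0114, adjusted p = 0.0636). Without ConvR mouse 4, 7 of the tests passed, and without GermFree mouse 3, 4 or 6, 5 did. With gene ends taken as 2 kb wide, 5 passed.

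Neighbouring sections of the small intestine were compared next. Between jejunum and duodenum the smallest p-values were at Ankrd33b, Ppp1r13b, a gene of a p53-binding protein, Pde9a, a cyclic GMP phosphodiesterase gene, Sstr5, a somatostatin receptor gene, and Peli2, a ubiquitin ligase gene. Ankrd33b (chromosome 15, 31297196 to 31297989) had 6.04 ± 1.61 CPM in the jejunum and 3.20 ± 1.16 in the duodenum (SD, n = 12), higher in 11 of 12 mice (edgeR adjusted p = 0.401), and Sstr5 had 11.4 ± 2.06 and 15.7 ± 2.63 (edgeR adjusted p = 0.871). With edgeR 0 of 95876 regions passed and 5184 had an unadjusted p under 0.05, and DESeq2 called 0. With the mouse as a block 15 passed, 14 of them lower in the jejunum, and Ankrd33b passed (adjusted p = 0.0312). No list passed, and the natural killer list had an adjusted p of 0.0565, 0.0105 with the mouse as a block and 0.356 with the block and an estimated correlation. Between ileum and jejunum the smallest p-values were at the pseudogene Speer6-ps1, at Prr12, at Cma2 and at Il1rl1, an interleukin receptor gene of mast cells and innate lymphoid cells. Il1rl1 (chromosome 1, 40458209 to 40458754) had 5.29 ± 1.52 in the ileum and 2.77 ± 0.965 in the jejunum (SD, n = 12), higher in 11 of 12 mice (edgeR adjusted p = 0.468). With edgeR 0 regions passed and 6484 had an unadjusted p under 0.05, DESeq2 called 0, and 1 passed with the mouse as a block. The natural killer list had an adjusted p of 0.153, 0.0355 with the mouse as a block and 0.332 with the block and an estimated correlation.

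Colon and ileum differed at many regions, each by a modest amount. Captured DNA was higher in the colon at Slc6a17, a vesicular amino acid transporter gene of neurons (chromosome 3, 107494954 to 107496416), with 10.3 ± 1.96 CPM against 6.08 ± 2.48 in the ileum (SD, n = 12; log2 0.90, SE 0.16; edgeR adjusted p = 0.00167), and at Rgs12, a regulator of G protein signalling (chromosome 5, 35005818 to 35006560), with 8.37 ± 2.78 against 4.55 ± 1.60. It was lower in the colon near Smarca4, the gene of a chromatin remodelling ATPase (chromosome 9, 21708009 to 21708451), with 2.40 ± 1.18 against 4.93 ± 1.73 (log2 -1.06, SE 0.22; edgeR adjusted p = 0.00376), at Slc22a22, an organic anion transporter gene (chromosome 15, 57291008 to 57291742; 3.499 ± 1.98 against 7.18 ± 2.82), and near Rfc3, a replication factor gene (chromosome 5, 151641599 to 151642168; 3.27 ± 1.29 against 6.81 ± 2.03). In the natural killer list 13 regions of 133 rose in the colon, all at 9 genes that include Klra1, Klra8 and H60b, and 20 passed when adjusted over the list alone. Klra1 (chromosome 6, 130364074 to 130369924) had 98.6 ± 31.1 against 73.5 ± 28.3, higher in 12 of 12 mice (log2 0.44, SE 0.10), and H60b did not pass without ConvR mouse 4 (log2 0.39) or 5 (0.37). The list's set test gave an adjusted p of 1.09e-06 with the preset correlation and an adjusted p = 0.0779 with an estimated correlation, which became 0.0219 with the mouse as a block, and 0.278 without the regions of the 12 clusters. None of the other 22 lists passed (smallest adjusted p = 0.0619), and 21 of their 1795 regions passed (1.17%, against 2.19% of all regions). With edgeR 2102 of 95876 regions passed, 1423 higher and 679 lower in the colon, and 14526 had an unadjusted p under 0.05. DESeq2 called 1185. With library totals in place of TMM factors the split was 1104 higher and 1002 lower, and with offsets fitted to abundance it was 984 and 781. With the mouse as a block 3447 passed. The colon libraries also had a larger share of counts on the Y chromosome, 1.92% ± 0.243 against 1.55% ± 0.242 (SD, n = 12), and with that share as a covariate, a check added after the data were seen, 1 region passed. Of the calls, 234 were on the Y chromosome and 233 of these were higher in the colon. In ConvR mice alone 0 regions passed with edgeR and in GermFree mice alone 1401 did. Without 1 mouse the count was 493 (GermFree 4), 729 (ConvR 2), 786 (ConvR 5), 1168 (ConvR 4) and 3223 (ConvR 3).

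**Figure D4:**
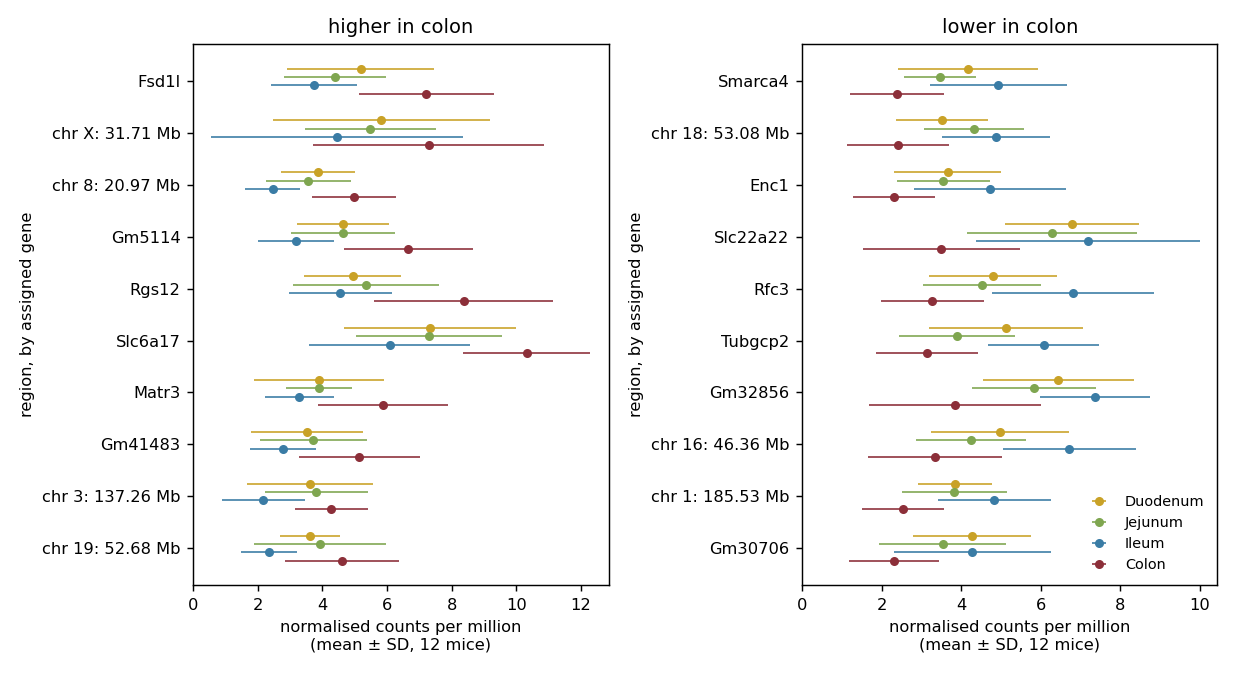
Normalised CPM (horizontal) of the 10 regions with the largest log2 difference upward and the 10 with the largest downward between colon and ileum, with points for the mean and bars for the SD of 12 mice in each of the 4 sections. At Slc6a17 the colon mean was 10.3 and the ileum mean 6.08, and near Smarca4 they were 2.40 and 4.93.

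Against the mean of the 3 small-intestinal sections, the colon had higher counts at a region of the T cell receptor alpha locus Tcra (chromosome 14, 53684415 to 53684839), with 6.04 ± 1.96 CPM against 2.94 ± 0.702 in the duodenum, 3.503 ± 1.59 in the jejunum and 3.56 ± 1.55 in the ileum (SD, n = 12; log2 0.85, SE 0.17; edgeR adjusted p = 0.00161). The same direction held at H60c, an NKG2D ligand gene (chromosome 10, 3247409 to 3251635; log2 0.39, SE 0.09; edgeR adjusted p = 0.00388). Counts were lower in the colon at Cars2, a mitochondrial tRNA synthetase gene (chromosome 8, 11532826 to 11533464; 3.42 ± 0.859 against 5.85 ± 2.13, 5.63 ± 1.43 and 5.82 ± 2.13), and at Scamp1, a vesicle membrane gene (chromosome 13, 94209991 to 94210453), in 12 of 12 mice. In the natural killer list 15 of 133 regions rose, at Klra1, Klra3, Klra8 and 6 further genes, and 22 passed when adjusted over the list alone (set test adjusted p = 1.28e-07; adjusted p = 0.0889 with an estimated correlation, 0.0111 with that and the mouse as a block; 0.201 without the regions of the 12 clusters). None of the other 22 lists passed (smallest adjusted p = 0.113). With edgeR 2295 regions passed, 1713 higher and 582 lower, 14407 had an unadjusted p under 0.05, and DESeq2 called 1375. The split was 1305 and 948 with library totals and 1234 and 774 with offsets fitted to abundance. With the mouse as a block 3627 passed, with the Y chromosome share as a covariate 1 did, and in ConvR mice alone 0 did. Without 1 mouse the count was 728 (ConvR 5), 1074 (GermFree 4), 1156 (ConvR 4), 1378 (ConvR 1), 1526 (ConvR 2) and 3869 (ConvR 3).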

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

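The explanations and tests below were added after the data were seen, except for the splits of the samples, for a single fold per cluster and for the germ-free state as the cause of the lower ileum regions, whose predictions were written before their tests. The tests on the levels of single mice were chosen with those levels in view.

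The first pattern weighed was the rise at 12 clusters, among them Klra, Raet1 and H60b, and the Btbd35f families. The germ-free state as the whole cause remained open for the 12 clusters as a set. At the sex chromosome clusters 1 of 7 GermFree mice lay inside the ConvR range in 4 of 4 sections, where the rule for exclusion asked for 4. This was mouse 3 at the 2 large X chromosome clusters and mouse 1 at the 2 clusters at the ends of X and Y. At the largest X chromosome cluster mouse 3 averaged 1356 CPM, against 903 to 1517 in ConvR mice. For these mice and clusters the values argue against the germ-free state as the whole cause, since the rise was absent. Of the 8 autosomal clusters 1, at Rasgrp3 and Fam98a, had GermFree mice inside the ConvR range in the means over the sections. In every section 2 of the 8 had all 7 above it. At Cr2 all 7 lay above it in the means, with mouse 3 barely so (533 CPM against a highest ConvR mean of 528). The 7 GermFree mice had the same order of means at Cr2 as at both large X chromosome clusters, and the reason was not tested. DNA copy number that differs between the mice could account for levels that stay with a mouse. Mice of a model differed beyond chance over the 4 sections at 12 of 12 clusters (8 in GermFree and 12 in ConvR mice). This test does not separate copy number from libraries of a mouse that captured less. At the Klra cluster ConvR mouse 3 had 1728 CPM in the duodenum and 2966 in the jejunum, with Y chromosome shares of 1.07% and 1.67%. At Cacna1b and Ehmt1 ConvR mice 1 and 4 had 438 and 897 CPM in the duodenum, with shares of 1.42% and 1.54%. The log2 difference was as even as in other windows at 3 clusters, and an uneven one decides nothing where copies within a family vary. It was close to a single fold at Cacna1b and Ehmt1 (SD 0.0461) and at Rasgrp3 and Fam98a (SD 0.0568). There 99.9% and 99.97% of windows had an SD at least as large. At Cacna1b and Ehmt1 the means over the sections ran from 457 to 987 CPM in ConvR mice and from 1275 to 1523 in GermFree mice. A difference in enrichment or depth that follows abundance was excluded as the whole cause, since 352 of 352 calls remained with offsets fitted to abundance, and other shifts of enrichment were not tested at the clusters. Copy number and methylation were not separated here, because no unenriched DNA was analysed, and the strain and colony of the mice, which are not given in the sources used here, stay open and untested.

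The second pattern was the difference between colon and ileum. A general shift of enrichment, read from the Y chromosome share, could account for the regions higher in the colon. Their median log2 difference went from 0.42 (SE 0.104) to 0.10 (SE 0.104) with that share as a covariate, so that 0 of 1423 calls were left because the difference itself shrank. The test cannot establish such a shift. Of these regions 233 were on the Y chromosome, so part of the shrinkage was fixed in advance. The share was also larger in the colon, so as a covariate it takes up part of any real difference between the sections. For the regions lower in the colon the median went from -0.55 (SE 0.143) to -0.45 (SE 0.161) with 1 of 679 calls left, and the test could not tell. All 679 kept their direction, but they were chosen as lower in these same libraries, so this decides nothing. A trend with abundance as the whole cause was excluded, as 1528 of 2102 calls (72.7%) remained with offsets fitted to abundance. A biological difference between the sections was not separated from the shift in either direction. The change of -0.45 that remained at the lower regions cannot establish one, since these regions were chosen for a fall.

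The third pattern was the 42 regions lower in GermFree ileum, such as Gm34259 and Rn7s2. The germ-free state as the whole cause was excluded, since at 2 of 42 regions all 5 ConvR mice lay above the GermFree mean by more than 2 SD. Reads from another source in single libraries were excluded as the whole cause, since in the 3 other sections the levels of these regions followed the mouse (permutation p = 0.00200), although in the colon the median ratio to the GermFree median was higher in GermFree mouse 4 (1.42) than in ConvR mouse 3 (1.22). A property of ConvR mice 1 and 3 stays open, as they had the 2 highest levels of the 12 mice in 2 of the 3 other sections, and without them 3 of 42 regions passed because the median log2 difference went from -1.51 (SE 0.323) to -0.51 (SE 0.302), with 3 ConvR mice left. A source shared by all sections of a mouse was not separated from such a property, and ConvR mouse 5 was raised too, at 28 of 42 regions in the ileum. The pattern was not confined to ConvR mice. GermFree mouse 2 had median ratios of 2.35 in the duodenum, 1.73 in the jejunum and 1.63 in the ileum, but 1 in the colon. In the duodenum and jejunum these were above ConvR mouse 5 (1.33 and 1.08).

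Among 124 groups of 4 to 10 samples, 12 had a sample far from the others, where chance flags about 1 in 20 groups. GermFree mouse 2 was far above the other GermFree mice, in CPM of the summed sections, at Gm34259 (15.2), Rn7s2 (28.1), Stx12 (8.46), Gm36011 (8.32) and 4 regions with no assigned gene, on chromosome 11 at 25099788 (21.2), chromosome 6 at 132463401 (11.5), chromosome X at 16318953 (8.75) and chromosome 7 at 78859521 (3.87). The GermFree duodenum library of mouse 6 had a total of 2.72 M counts, above the next by a wide gap. The GermFree ileum library of mouse 4 had a low share of counts on the Y chromosome (1.15%) and on mitochondrial and unplaced sequence (1.31%). The ConvR colon library of mouse 3 had a low share on the Y chromosome (1.25%).

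A difference between GermFree and ConvR mice that varied with the section was found at 13 regions in the fit with the mouse as a block, by a test of the difference itself, and at 0 without the block. Besides Gm34259, Gm24105 and Il5 these were at 1700072O05Rik, Cacng2, Lrrc69, Gpihbp1, Ybx3, Cnih3, Zfp266 and Vwa1 and at 2 places with no gene within 50 kb. ConvR mice 1 and 3 had the 2 highest levels of the 12 mice at 13 of the 13 regions in the duodenum and ileum, 12 in the jejunum and 1 in the colon, and in the block fit without them, a test added after these levels were seen that leaves 3 ConvR mice, 0 of the 13 passed (smallest adjusted p = 0.99981).

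Other splits of the mice, with the same numbers in each group, were drawn to see how often a split gave as many passing regions as the real one. In the jejunum (281), ileum (312) and colon (402) 1 of 100 splits did, the real one, and the highest other counts were 212, 188 and 313. In the duodenum 2 of 100 did, the real one (349) and a split with 862, and in the sums 2 of 100, the real one (455) and a split with 1604 that joined ConvR mice 1, 3 and 5 with GermFree mice 4 and 6. The split with 862 joined ConvR mice 1, 3, 4 and 5 with GermFree mouse 6. The lowest Y chromosome shares in the duodenum were in this group: 1.07% (ConvR 3), 1.38% (GermFree 6), 1.39% (ConvR 5) and 1.42% (ConvR 1). In the ileum the lowest were 1.06% (ConvR 3), 1.15% (GermFree 4) and 1.34% (ConvR 5), all in the group of the split with 1604. Both splits point to a structure among the mice that goes with this share in these sections, and its source was not tested. Between sections 1 of 24 splits reached the real count for colon against ileum (2102, highest other 0) and for the colon against the small intestine (2295, highest other 1). For jejunum against duodenum, ileum against jejunum and the variation by section the real count was 0, which 24 of 24 splits reached.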

How the results depend on the processing

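Alternatives without the regions of the 12 clusters, with scores at or above the median, without ConvR mice 1 and 3 (also with the mouse as a block), with the Y chromosome share as a covariate, and the list results without each mouse or with a block were added after the data were seen; the others were planned. The rise at the Klra, Raet1, H60b and X chromosome families kept its direction and its call at the named regions under the scalings, filters and blocks in edgeR, while with DESeq2 some X chromosome regions, such as Gm14356 in the duodenum and jejunum, did not pass. Of the named calls higher in GermFree mice 0 of 21 in the duodenum, 2 of 19 in the jejunum, 2 of 20 in the ileum, 1 of 22 in the colon and 0 of 19 in the sums were lost when any 1 mouse was left out. Of the named lower calls 10 of 10, 8 of 10, 4 of 11, 10 of 11 and 9 of 11 were lost. Of the named calls between colon and ileum 15 of 23 higher and 14 of 22 lower ones were lost without some mouse. The cause was not tested for the changes below, except where fewer regions or mice were tested.

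With the DESeq2 Wald test 221 regions passed in the duodenum, 143 in the jejunum, 163 in the ileum, 246 in the colon, 1185 for colon against ileum and 1375 for colon against the small intestine. With autosomes only the counts were 195, 122, 158 and 221, and 276 in the sums. Without the regions of the 12 clusters they were 30, 29, 41 and 32, and 67 in the sums. Without the 2 GermFree mice whose title code no ConvR mouse has they were 212 in the duodenum, 180 in the ileum and 264 in the colon, and with all 48 libraries in 1 fit 179 in the jejunum. Without 1 mouse they ranged from 284 to 467, 239 to 297, 241 to 360, 341 to 429 and 411 to 517 in the duodenum, jejunum, ileum, colon and sums, from 493 to 3223 for colon against ileum, from 728 to 3869 for colon against the small intestine, and stayed at 0 for the other 3 comparisons.

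For colon against ileum and colon against the small intestine 0 and 0 regions passed in ConvR mice only, 1401 for colon against ileum in GermFree mice only, and 1 and 1 with the Y chromosome share as a covariate. With the mouse as a block 15 regions passed between jejunum and duodenum, 1 between ileum and jejunum, 3447 and 3627 in the 2 colon comparisons and 13 for the variation by section, 0 without ConvR mice 1 and 3; Ankrd33b passed (log2 0.93), 4 lists passed between sections, and the natural killer list passed between jejunum and duodenum (0.0105) and ileum and jejunum (0.0355). With the block and an estimated correlation it did not pass between jejunum and duodenum (0.356) or ileum and jejunum (0.332), and it passed in the colon comparisons (0.0219 and 0.0111). The block changed no other call between sections. GermFree and ConvR mice share numbers and title codes, whose meaning is not given in the sources used here: libraries of the same number had a correlation over 0.1 in 0 of 20 pairs (median -0.0115) and those of the same code in 0 of 20 (median 0.00126), and blocks gave 344, 228, 230, 377 and 420 regions by number and 282, 229, 263, 344 and 431 by code.

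The lists passing between GermFree and ConvR mice numbered 5 over the 5 comparisons, 5 to 7 without 1 mouse and 0 without the clusters, where the natural killer list had adjusted p-values of 0.622, 0.738, 0.751 and 0.681 in the duodenum, ileum, colon and sums, and turned direction in the jejunum (0.942). The clusters were chosen for this difference, so leaving them out was bound to weaken the natural killer list. Without 1 mouse its adjusted p lay between 3.26e-38 and 5.86e-28, 9.34e-27 and 4.11e-14, 9.02e-43 and 1.22e-21, 2.13e-41 and 8.51e-35, and 4.29e-42 and 5.05e-30 in the 5 comparisons. Between sections 2 lists passed, 0 with an estimated correlation, 15 with fry, 5 with regions within 1 kb of a gene end, 0 without the clusters and 2 to 4 without 1 mouse. For the natural killer list these settings gave, for colon against ileum and against the small intestine, 0.0779 and 0.0889 (estimated), 0.278 and 0.201 (without clusters), 4.35e-07 to 2.26e-05 and 4.12e-08 to 7.04e-06 (without 1 mouse), and, for jejunum against duodenum and ileum against jejunum, 0.00430 and 0.00415 (gene ends), 0.00862 to 0.268 and 0.0541 to 0.536 (without 1 mouse). Of the tests of shares 5 passed with gene ends of 2 kb and 0 to 7 without 1 mouse.

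Without ConvR mice 1 and 3 the log2 difference turned direction at Gm36011 (0.0573) and chromosome 6 at 132463401 (0.13) in the duodenum, at chromosome 8 at 121687912 (0.45), Gm34259 (0.21), Rn7s2 (0.13) and Auts2 (0.21) in the jejunum, at chromosome 8 at 121687912 in the colon (0.00399) and at Stx12 in the sums (0.00828). With the Y chromosome share as a covariate it turned at Klra9 (-0.00705) and at 2 regions of Abcg2 (-0.0272 and -0.0162) for colon against ileum, and at Abcg2 (-0.00720) for colon against the small intestine.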

Other observations

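The hypothesis and the gene groups below were chosen after the data were seen. Between colon and ileum, single regions of immune and epithelial genes passed the edgeR test although their lists did not. Captured DNA was lower in the colon inside Ifngr2, an interferon gamma receptor gene (chromosome 16, 91556621 to 91560313; 16.5 ± 3.11 against 23.3 ± 3.32 CPM, SD, n = 12; log2 -0.53, edgeR adjusted p = 0.00167), and inside Spib, a transcription factor gene of B cells and M cells (46.3 ± 8.31 against 56.5 ± 6.73; log2 -0.29, edgeR adjusted p = 0.0307). It was higher in the colon inside H2-D1, a classical MHC class I gene (chromosome 17, 35265364 to 35269401; 41.2 ± 7.41 against 30.5 ± 6.21; log2 0.41, edgeR adjusted p = 0.00487), inside Ugt1a1, the bilirubin glucuronidation gene (chromosome 1, 88211598 to 88228779; 251 ± 35.6 against 195 ± 26.7; log2 0.36, edgeR adjusted p = 0.0103), and inside the efflux transporter gene Abcg2 (133 ± 15.7 against 107 ± 22.8; log2 0.31, edgeR adjusted p = 0.0311).

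In the 22 lists other than the natural killer list 21 of 1795 regions passed (1.17%), against 2102 of 95876 over all regions (2.19%), so these are single calls. Genes that write or read chromatin marks had 3 passing regions of 99 in their list. Regions inside the maintenance methyltransferase gene Dnmt1 (chromosome 9, 20906982 to 20910308; 16.1 ± 4.64 in the colon against 21.4 ± 2.86 in the ileum, SD, n = 12; log2 -0.38, edgeR adjusted p = 0.0239) and the histone demethylase gene Kdm2b (9.33 ± 2.42 against 13.5 ± 3.59; log2 -0.54, edgeR adjusted p = 0.0138) were lower in the colon, and a region inside the histone methyltransferase gene Kmt2a (14.1 ± 2.57 against 9.94 ± 1.57; log2 0.48, edgeR adjusted p = 0.0260) was higher in 12 of 12 mice. Against the 3 small-intestinal sections, a region inside Dnmt3a, a de novo methyltransferase gene (chromosome 12, 3894713 to 3897131), was lower in the colon (log2 -0.34, edgeR adjusted p = 0.0466). With the Y chromosome share as a covariate none of these regions passed, and the log2 difference was -0.54 at Ifngr2, -0.53 at Kdm2b, -0.26 at Dnmt1, -0.21 at Spib, -0.19 at Dnmt3a, 0.17 at Kmt2a, 0.12 at H2-D1, 0.04 at Ugt1a1 and -0.02 at Abcg2. The calls at Ifngr2 and at the H2-D1 region given above were kept without any 1 mouse, while another H2-D1 region (chromosome 17, from 35271359) did not pass without ConvR mouse 1, 2 or 5 or GermFree mouse 4. Those lost without 1 mouse were Kdm2b (ConvR 2 or GermFree 4), Ugt1a1 (ConvR 2 or 4 or GermFree 4), Abcg2 (ConvR 2 or 5 or GermFree 4), Kmt2a (ConvR 1, 4 or 5 or GermFree 4 or 7), Spib (ConvR 1, 2 or 5 or GermFree 1, 4 or 5), Dnmt1 (ConvR 1, 2, 4 or 5 or GermFree 4, 5 or 7) and Dnmt3a (ConvR 1, 3, 4 or 5 or GermFree 1, 3, 4 or 5).

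The clusters near the ends of the X chromosome (169970560 to 170022741, at Mid1) and of the Y chromosome (90717480 to 90811171) rose and fell together over the mice. A single sequence shared by X and Y in their pseudoautosomal part would give nearly the same order of mice at both ends. Over the 7 GermFree mice the levels had a Pearson correlation of 0.996 (exact permutation p = 0.000198) and 0.983 without the 2 mice farthest from the rest (n = 5). Over the 5 ConvR mice it was 0.973, where mice 1 and 2 changed places between the ends, as did mice 4 and 5 (Spearman 0.80). One shared sequence whose amount differs between mice could give these values, but they cannot establish it. The GermFree mice also had a common order at the Cr2 cluster on chromosome 1 and at both large X chromosome clusters, which are separate places.

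Mice of the same model also differed from each other at many regions. With the sections as replicates of a mouse, 496 regions differed among GermFree mice, 254 of them in the 12 clusters, and 1052 among ConvR mice, 133 of them in the clusters.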
